A study of Mus musculus with 4 samples.

How the data were processed

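The series holds 4 single-cell RNA-seq libraries of mouse fetal pancreas, 1 for each combination of age (E13.5, E15.5) and genotype (WT, KO). Per the labels' protocols, tissue was dissociated with TrypLE, cells were labelled for EpCAM and purified by flow cytometry, and libraries were sequenced as paired-end reads on an Illumina NovaSeq instrument. The number of embryos per library, the capture platform and the library kit are not given in the sources used here. Groups were taken from the sample titles, and no label gives replicates.

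The files deposited by the authors that were used here hold no measured values. Each has no header and 2 columns, an Ensembl gene identifier and a symbol, in identifier order with no identifier repeated. The unit is therefore whether a gene is listed. The submitters' processing notes name Seurat and the genome build mm10, without a Seurat version. The aligner, the annotation release, the filters on cells and genes, and the rule that put a gene on a list are not given in the sources used here. The complete lists hold 25463 to 26341 genes of the 55536 in the annotation and differ between libraries, so each list is a subset and not the whole annotation. Whether that subset is every gene with a read, or every gene above a minimum number of cells, is not stated. A list grows with the number of cells and reads as well as with the kinds of cells, and none of these is known here. Because there are no counts, no expression level, cell type share, interval or limit of detection could be given, and no test on counts was run. The analysis plan had foreseen both kinds of file, and the part for gene lists was used.

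The E15.5 WT list ends in the middle of an identifier after 167 complete lines. Comparisons with it used only identifiers up to its last complete line, a stretch with 187 annotated genes. Its remaining genes were not analysed here. In identifier order this stretch is 186 protein-coding genes and 1 other, so it says next to nothing about non-coding genes.

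Gene types and coordinates came from GENCODE mouse release M21 on GRCm38, the assembly that mm10 names. Of the 29652 identifiers in any complete list, 29604 matched this annotation by identifier and 48 did not. The 48 have no type here and enter only the counts over all genes. For 738 matched identifiers the symbol differed from the annotation, and symbols are printed as the deposited lists give them. No identifier had different symbols in different lists. In the lists, 44 symbols carry an appended number of the kind that marks a repeated name. Genes not of the type protein-coding are called non-coding, pseudogenes and immune receptor segments included. A non-coding gene was placed inside a coding gene when its whole span lay within the span of a protein-coding gene, and outside when it overlapped none.

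For each comparison the genes listed in 1 library only and in both were counted, and the share in both was taken over the genes in either. Gene lists for 7 pancreatic epithelial cell types, 7 other cell types or tissues and 5 pathways, with 313 symbols in all, were fixed before the data were examined. Of these symbols 309 were in at least 1 complete list. Amy2a5 was in none, and Selm, Whsc1 and Whsc1l1 are listed under their present symbols Selenom, Nsd2 and Nsd3. The number of members listed in 1 library only was set beside 10000 random lists of the same size, drawn from the genes in either library and, as an alternative, from the protein-coding ones, as a description of these libraries. Genes are not replicates, and 1 library per group allows no p-value between groups.

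The genes named were Setd2, then list members that differed, then up to 10 genes listed in both libraries of one genotype or age and in neither of the other, protein-coding first and longest first. Because the E15.5 WT list is cut, the last step was applied to the 3 complete lists, a change made after the data were seen. Genes that differed within the stretch covered by all 4 lists were named in full, also after their values were seen. Some genes that the rule would name are not reported here.

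For the closing part, spreads over chromosomes were computed with a delete-one jackknife over the autosomes, the X chromosome and the remaining sequences. They describe how evenly a pattern runs over the genome and do not cover variation between libraries. The genes that only a pair of complete lists held were totalled over the pairs. This total was split into expected numbers from the genes listed once, with 1 factor per list and a detectability per gene. A surplus in 1 pair therefore lowers the ratios of the others. These steps were tested on simulated lists of 29652 genes. With a depth difference alone the non-coding minus coding log2 ratio was -0.10 ± 0.097 (jackknife SE), and with non-coding genes raised it was 1.55 ± 0.097. The pair ratio was 1.02 ± 0.043 at similar depths with no age effect and 1.52 ± 0.047 with one. It was 1.18 ± 0.037 with no age effect when E15.5 KO was simulated at a relative depth of 0.5, so a ratio above 1 does not by itself exclude a shallower library. Neither that depth nor the other simulated depths and detectabilities were set from the real lists. In the simulations any read listed a gene, while the real rule is unknown. Alternatives were matching by symbol, restriction to protein-coding genes, removal of predicted and mitochondrial genes, merging of name suffixes, and older symbols. Those that need counts or cells could not be run. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.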

Results

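Single-cell RNA sequencing libraries were made from EpCAM-labelled, flow-sorted cells of the fetal mouse pancreas at E13.5 and E15.5 of embryonic life. EpCAM is an epithelial surface protein. At each age there was 1 library from Setd2 f/f embryos without the deletion (WT) and 1 from embryos that carried Pdx-Cre, a recombinase active in the pancreas, together with Setd2 f/f (KO), which makes 4 libraries in 4 groups. Setd2 encodes the methyltransferase that places trimethylation on lysine 36 of histone H3. The data used here were the gene list of each library, in which a gene was either listed or not listed. Counts, cells and expression levels were not analysed here, so the sequencing depth behind each list is unknown. The E13.5 WT list held 25463 genes, the E13.5 KO list 26341 and the E15.5 KO list 25474. The E15.5 WT list ended inside a gene identifier after 167 complete entries, and comparisons with it cover only the stretch of identifiers up to its last entry. With 1 library per group there was no replicate check, and no p-value was computed. A gene that is listed may still have had a very different level in each library.

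Setd2 itself (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633, mm10/GRCm38) was listed in 3 of the 3 complete lists, those of E13.5 WT, E13.5 KO and E15.5 KO. Its identifier lies beyond the end of the E15.5 WT list. A listing has no level and does not separate reads inside the deleted part from reads outside it, so it does not check the genotype labels. The pancreatic transcription factors and hormones were shared: Pdx1, Ptf1a, Sox9, Nkx6-1, Neurog3, Ins1, Ins2, Gcg, Sst, Ppy and Ghrl were in every complete list. Of the 104 markers of pancreatic epithelial cells that any complete list held, 102 were in E13.5 WT, 102 in E13.5 KO and 104 in E15.5 KO.

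The comparison of E13.5 KO with E13.5 WT asks which genes were listed in the sorted cells of the library labelled KO and of that labelled WT at this age. No marker of pancreatic epithelial cells was listed in 1 genotype only. The 16 trunk and ductal progenitor markers, the 12 markers of multipotent progenitors, the 19 of endocrine progenitors, the 20 of beta cells, the 14 of alpha cells and the 11 of delta, PP and epsilon cells were listed in both libraries, and so were 22 tip and acinar markers. The same held for the pathway lists: 23 genes of histone H3 lysine 36 methylation and its readers, 25 cell cycle genes, 27 Wnt genes, 20 Notch genes and 19 genes of apoptosis and p53 were in both. Both lists also held each of the markers of mesenchyme (20), mesothelium (8), endothelium (12), erythroid cells (13), immune cells (14) and neural crest and glia (13).

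The 2 members of the gene lists that differed at E13.5 were both in the WT list and absent from the KO list, and both are mucosal genes of the stomach. Muc5ac, a secreted gel-forming mucin of the gastric surface (chromosome 7, 141788972 to 141819231), was listed in E13.5 WT and in E15.5 KO. Tff1, a trefoil peptide of the stomach (chromosome 17, 31161395 to 31165277), was listed in E13.5 WT alone among the complete lists. The other 13 of the 15 markers of liver, stomach and gut epithelium were in both E13.5 lists. Among them were Tff2, Cym and Sox2 of the stomach and Alb and Afp of the liver. For this list, 77.4% of random protein-coding lists of its size had fewer differences (mean 0.91). In all, 2 of 307 list members differed, against a mean of 50.2 in random lists of the same size and 18.6 in random lists of protein-coding genes. Random lists could not be matched on expression, which the gene lists do not give.

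**Figure D1:**
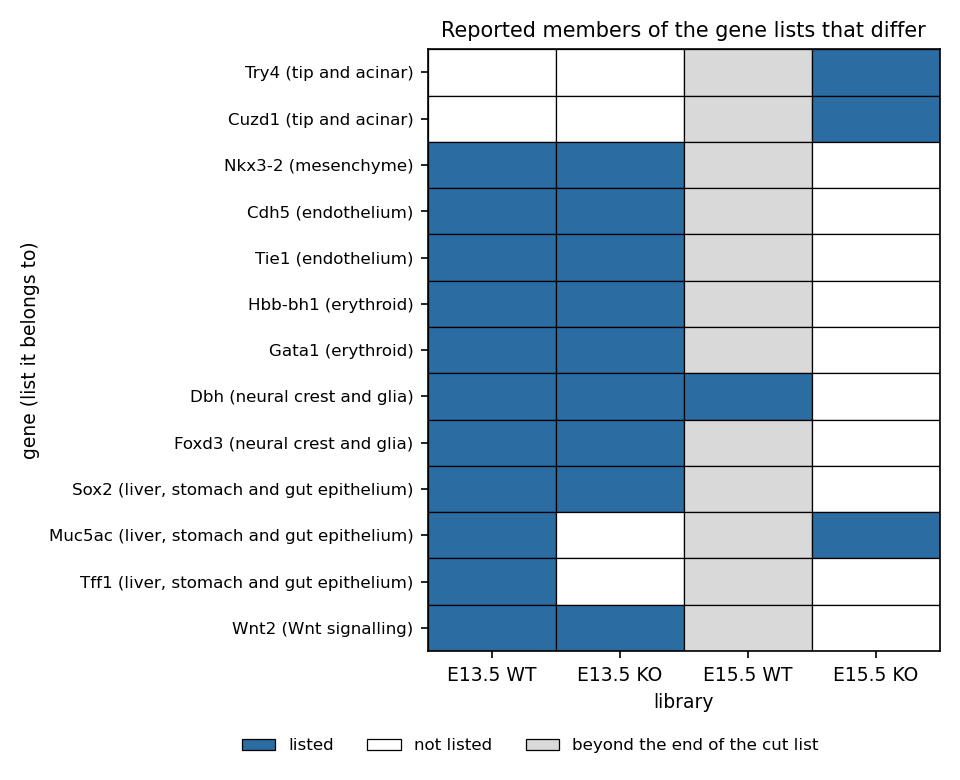
Members of the marker and pathway lists, among those reported by name, that were missing from at least 1 complete gene list, drawn with a line per gene with its list in brackets, against the 4 libraries on the horizontal axis. A blue cell is a listed gene, a white cell a gene not listed, and a grey cell a gene beyond the end of the E15.5 WT list. Of the genes drawn, Muc5ac and Tff1 differ between the E13.5 libraries, while 9 genes listed at E13.5 in the KO library are missing from the E15.5 KO library. These include Wnt2 of the Wnt list, so they are not the same 9 as the markers of other cell types in the text.

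Outside these lists, the 2 genotypes at E13.5 differed mainly in non-coding genes. Of 28204 genes listed in either library, 23600 (83.7%) were in both, 2741 were in the KO list only and 1863 in the WT list only. Among protein-coding genes 93.9% were shared, with 560 in KO only and 514 in WT only. Among non-coding genes, a class that here takes in pseudogenes and small RNAs, 66.5% were shared, with 2173 in KO only and 1347 in WT only. Processed pseudogenes, which are reverse-transcribed copies of other genes, were listed 652 times in KO only and 352 times in WT only. Genes that the annotation marks as still to be tested experimentally (TEC) numbered 390 in KO only and 176 in WT only. Long intergenic RNAs numbered 444 and 343, and antisense RNAs 265 and 190. Processed pseudogenes can take reads from their parent genes, and antisense genes can take reads from the gene opposite where the strand is not used, so single members of these classes are uncertain. Non-coding genes that lay inside a protein-coding gene on its strand were listed 492 times in KO only and 211 times in WT only, a ratio of 2.33, and those outside protein-coding genes 1181 and 798 times, a ratio of 1.48.

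**Figure D2:**
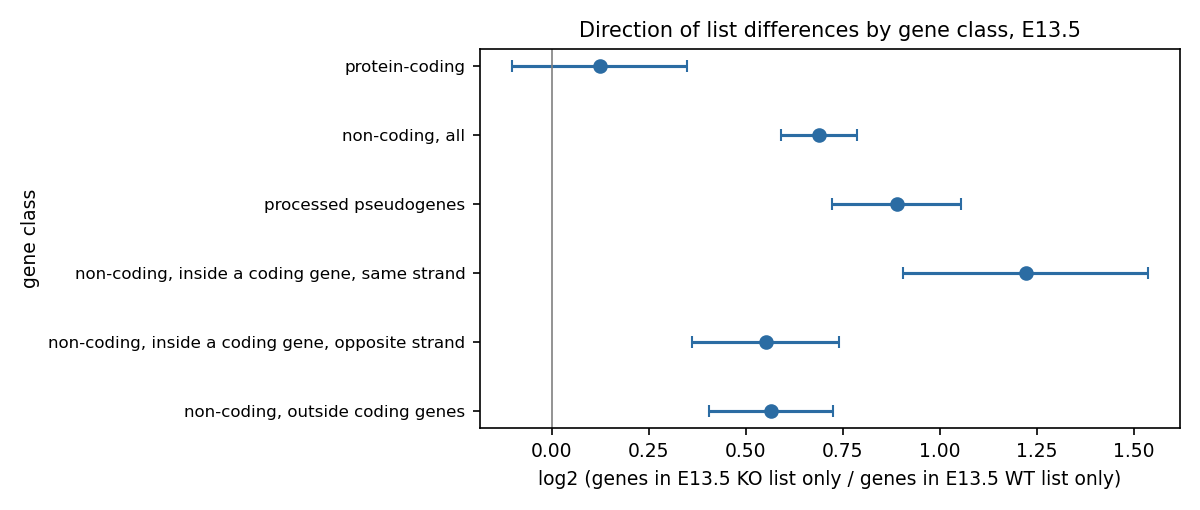
Log2 ratio of genes in the E13.5 KO list only to genes in the E13.5 WT list only (horizontal axis) for classes of genes (vertical axis). Points are the ratios and bars are 2 jackknife standard errors over chromosomes to each side, which do not cover variation between libraries. Protein-coding genes lie at 0.12 and non-coding genes inside protein-coding genes on the same strand at 1.22.

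**Figure D3:**
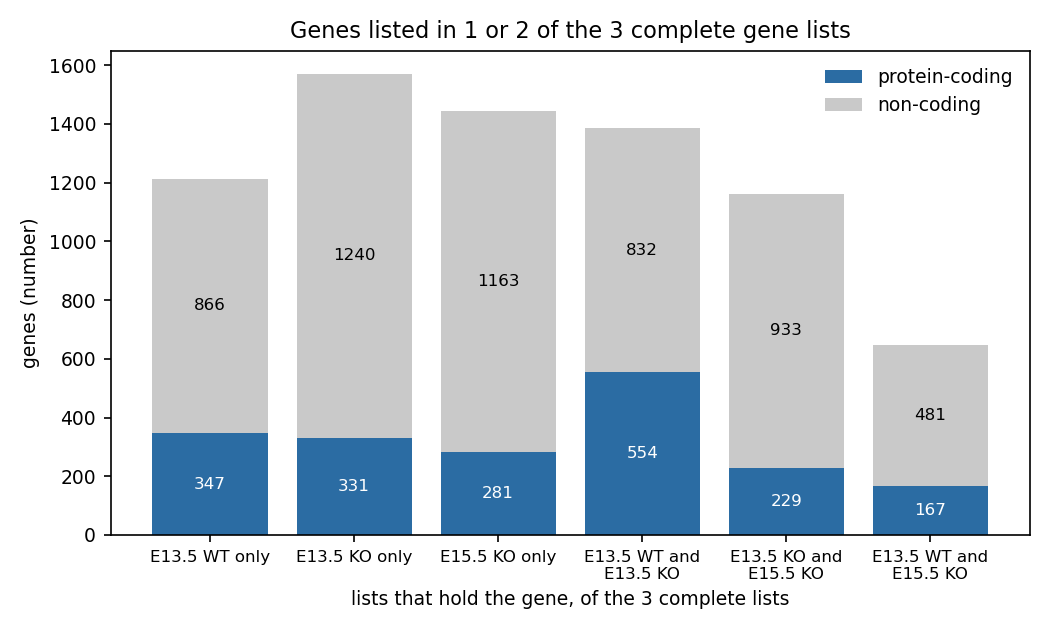
Number of genes (vertical axis) held by 1 or 2 of the 3 complete lists, by the lists that hold them (horizontal axis), with protein-coding genes in blue and non-coding genes in grey. A further 22210 genes were in all 3 lists. The 554 protein-coding genes shared by the E13.5 lists and missing at E15.5 KO form the largest protein-coding group shown.

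Protein-coding genes that both KO lists held and the E13.5 WT list did not numbered 229. The genes that only a pair of complete lists held were split among the pairs from the genes listed once, with 1 factor per list. This gave 289 for the KO pair, and the 229 were 0.79 times that number. The pairs divide a fixed total, so the surplus of the E13.5 pair (1.55) lowers the other ratios. The pair of E13.5 WT and E15.5 KO stood at 0.55. Whether the KO lists shared a surplus therefore cannot be read from the 0.79. Among the longest of the 229 were Gpr158, Grin2b, Gm11639, Esr1, Ccdc7a, Tmem232, Glra3, Pcdha11 and Slc24a4. Esr1 (chromosome 10, 4611593 to 5005614) encodes the estrogen receptor alpha. Grin2b (chromosome 6, 135713233 to 136173511) encodes an NMDA-type glutamate receptor subunit and Glra3 (chromosome 8, 55940460 to 56130070) a glycine receptor subunit. Protein-coding genes in the E13.5 WT list and in neither KO list numbered 347. The 10 longest were Il1rapl2, Thsd7b, Rp1, Trdn, Adamtsl3, Glra2, Tll1, Gm3005, Iqcj and Impg1. Trdn (chromosome 10, 33080554 to 33476709) encodes triadin of the muscle calcium release complex, Rp1 (chromosome 1, 3999557 to 4409241) a photoreceptor protein, and Glra2 (X chromosome, 165129017 to 165327393) another glycine receptor subunit. Pcdha11 belongs to the clustered protocadherins, which share their last exons, so a listing of this gene is uncertain. Both sets rest on the single E13.5 WT library, the 1 WT list that was complete.

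At E15.5 the genotypes could be compared over a stretch with 187 annotated genes, 186 of them protein-coding. In this stretch 169 genes were listed in E15.5 KO and 167 in E15.5 WT, and 164 of the 172 listed in either were in both (95.3%). Ins2 and Gcg, the insulin and glucagon genes, Sox9 of the progenitors and ducts, Cdh1 of epithelia, Btbd17 of the endocrine progenitor list, and Ccnd2, Axin2 and Tcf7 were in both. The 3 genes in E15.5 WT only were Clec2g, Myf5 and Dbh. Myf5 (chromosome 10, 107482908 to 107486134) is a muscle determination factor that neither E13.5 list held. Dbh (chromosome 2, 27165233 to 27183200), the dopamine beta-hydroxylase of sympathetic neurons, was in both E13.5 lists as well. The 5 genes in E15.5 KO only were Itgb2l, Slfn4, Glra1, Grm6 and Scn4a. Of these, Glra1 (chromosome 11, 55514238 to 55608198) was in no other list, while Itgb2l, Slfn4, Grm6 and Scn4a were in both E13.5 lists. Over the same stretch the E13.5 lists differed in 2 genes, Clec2g and Fasl, both in KO only.

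In the KO, the comparison of E15.5 with E13.5 asks how the sorted pancreas changed with age. The E15.5 KO list held 2 acinar genes that the E13.5 KO list did not, about the mean of 1.84 in random protein-coding lists of that size (44.3% had fewer), and it lacked 9 markers of other cell types. Try4 (chromosome 6, 41302269 to 41305532), a trypsinogen, and Cuzd1 (chromosome 7, 131308554 to 131322292), a zymogen granule protein, were listed at E15.5 and not at E13.5, which brought the tip and acinar list from 22 to 24 of its 24 listed members. Trypsinogen genes are near-identical copies, so the listing of Try4 is uncertain. The other pancreatic epithelial lists did not differ between the ages. Of the 93 markers of other cell types listed at either age in KO, 9 were listed at E13.5 only and 1, Muc5ac, at E15.5 only.

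The 9 markers came from 5 cell types. The neural crest and glia list lacked 3 of 13 members at E15.5, among them Dbh and Foxd3 (chromosome 4, 99656299 to 99658622), a transcription factor of the neural crest. Dbh is the 1 of these 9 markers that the E15.5 WT list covers, and it was listed there, as were all 3 members of the other cell type lists in that stretch. The endothelium list lacked 2 of 12, Cdh5 (chromosome 8, 104101625 to 104144511), which encodes VE-cadherin, and Tie1 (chromosome 4, 118471191 to 118490061). The erythroid list lacked 2 of 13, the embryonic globin Hbb-bh1 (chromosome 7, 103841637 to 103843164) and Gata1 (X chromosome, 7959260 to 7978071). The mesenchyme list lacked Nkx3-2 (chromosome 5, 41761483 to 41764501), and the liver, stomach and gut list lacked Sox2 (chromosome 3, 34650405 to 34652461), a foregut and stomach factor. Immune (14 of 14) and mesothelium (8 of 8) markers were complete at both ages. Most markers of each of these types, such as Pecam1, Kdr, Col1a1, Hba-a1 and Sox10, were listed at both ages. Taking the other cell type lists together, 10 members differed, more than in 83.0% of random lists of protein-coding genes of that size (mean 7.09) and more than in 2.42% of random lists drawn from all genes (mean 16.6). Among pathway genes 1 of 114 differed: Wnt2 (chromosome 6, 17988940 to 18030585), a Wnt ligand, was listed at E13.5 only. Age, sort and library coincide in this comparison, and the E15.5 KO list held fewer protein-coding genes than either E13.5 list. The cell cycle, Notch, apoptosis and p53, and histone H3 lysine 36 lists did not differ.

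Over all genes, 82.2% of the 28438 genes listed at either age in KO were in both lists, with 2964 at E13.5 only and 2097 at E15.5 only. The excess at E13.5 was larger among protein-coding genes, with 885 at E13.5 only and 448 at E15.5 only, than among non-coding genes, with 2072 and 1644. Of the 885, 554 were also in the E13.5 WT list. The 10 longest of those 554 were Nrxn3, Il1rapl1, Lrrc4c, Dcc, Cdh18, Malrd1, Dscam, Adarb2, Iqcm and Lhfpl3. Nrxn3 (chromosome 12, 88722876 to 90334935), a neurexin, and Lrrc4c (chromosome 2, 96318169 to 97631666) encode synaptic adhesion proteins, and Dcc (chromosome 18, 71253634 to 72351069) and Dscam (chromosome 16, 96590840 to 97170752) encode axon guidance receptors. The E15.5 KO list alone held 281 protein-coding genes. The 10 longest were Gm15155, Gm45194, Pcdha5, 4931428L18Rik, Olfm3, Slc22a14, Pcdha11_2, Cntnap3, Pkd1l1 and 5430419D17Rik, of which Pcdha5 and Pcdha11_2 share exons with other clustered protocadherins. The order by length puts long genes first in each of these sets.

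In the WT, the ages could be compared only over the stretch that the E15.5 WT list covers. Of 176 genes listed at either age there, 165 (93.8%) were in both, 9 were at E13.5 only and 2, Clec2g and Myf5, at E15.5 only. Lhx2, Gabra2, Dnmt3l, Hoxa10 and S100a5, 5 of the 9, were listed at E13.5 in both genotypes and at E15.5 in neither. Lhx2 (chromosome 2, 38339281 to 38369733) and Hoxa10 (chromosome 6, 52231197 to 52240854) are homeobox transcription factors, Gabra2 (chromosome 5, 70957597 to 71095849) is a GABA receptor subunit, and Dnmt3l (chromosome 10, 78041947 to 78063622) is a cofactor of DNA methylation. No gene in this stretch was listed at E15.5 in both genotypes and at E13.5 in neither. No gene separated both KO lists from both WT lists, and 1 gene, Clec2g, split the 4 libraries across age and genotype. Of the 178 genes listed in any library over this stretch, 164 were in all 4 lists.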

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

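Clec2g (chromosome 6, 128934381 to 128984707), a C-type lectin gene, was the 1 gene of the stretch covered by all 4 lists whose listing went opposite ways between genotypes at the ages: at E13.5 it was listed in KO and not in WT, and at E15.5 in WT and not in KO. The difference was not tested, since each group has 1 library. No explanation was weighed for a single gene.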

How the results depend on the processing

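Matching by symbol, merging of dot or dash suffixes and older symbols changed no value by more than 1.5 times, and Setd2 was found in the same 3 lists by identifier. Alternatives that need counts or cells were not run. No paired analysis was possible because each group has 1 library. With protein-coding genes only, the E13.5 KO list held 17154 genes and the E15.5 KO list 16717, and without predicted and mitochondrial genes they held 17391 and 16975. The E13.5 lists then differed in 560 genes in KO only and 514 in WT only (93.9% shared), or in 642 and 586 (93.2% shared) without predicted genes. The KO lists differed in 448 genes at E15.5 only and 885 at E13.5 only (92.4% shared), or in 540 and 956 (91.7% shared). These smaller counts follow from the fewer genes kept. More genes were in KO only than in WT only at E13.5, and more at E13.5 than at E15.5 in KO, under each of these settings. The excess of KO-only over WT-only genes at E13.5 shrank, however, from 2741 against 1863 to the values above. Among protein-coding genes its log2 ratio was 0.12 ± 0.11 (jackknife SE over chromosomes), within 2 SE of 0. Chosen after the data were seen, non-coding genes alone gave 66.5% shared at E13.5 and 65.6% between the KO ages. In the stretch of the E15.5 WT list alone, the E13.5 lists differed in 2 genes in KO only and 0 in WT only (98.9% shared), and the KO lists in 1 at E15.5 only and 8 at E13.5 only (94.9% shared). The place of the other cell type lists among random lists depended on the genes drawn: at E13.5 it moved from 0% to 2.13% of random lists with fewer differences, and between the KO ages from 2.42% to 83.0%. The depth of each library is unknown, so a gene missing from a list may have been missed rather than absent.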

Other observations

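Protein-coding genes grouped by the letters that start their symbols, a grouping chosen after the data were seen, added other gene groups to the comparison of the KO ages. There were 243 families with 10 or more listed members. The Cd family, set by symbol and not by cell type, showed 14 genes at E13.5 only, against 1 at E15.5 only, Cd209c. Among the 14 were Cd3d, Cd5l, Cd209a and Cd300c. Of the 14 markers on the fixed immune list, 0 were at E13.5 only. More Cd members differed, in either direction, than in 99.8% of random protein-coding lists of 88 genes. This does not set the family apart, since the olfactory receptor, Vmn vomeronasal receptor and Defb defensin families stood at 100% in the same comparison, and the 14 against 1 was not tested. Solute carriers showed 26 genes at E13.5 only and 7 at E15.5 only, with more differences than in 87.7% of random lists. Transmitter transporters were on both sides, with Slc18a3 and Slc32a1 at E13.5 only and Slc6a3 at E15.5 only among the KO lists, though the E13.5 WT list held it too. The keratins showed 9 at E13.5 only, Krt5, Krt13 and Krt14 of stratified epithelia among them, and 3 at E15.5 only. These families were picked after their values were seen, and others leaned to E15.5. The Krtap family showed 6 at E15.5 only and 2 at E13.5 only, and the Tex family 6 and 1. Across all 1333 protein-coding genes listed at 1 KO age, 33.6% were at E15.5. Olfactory receptor genes showed 44 at E13.5 only and 22 at E15.5 only, close to that share.

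Between genotypes at E13.5, 245 families were counted, and those named here were picked after their values were seen. Of the 1074 protein-coding genes listed in 1 genotype only, 52.1% were in KO, and no direction of a family was tested against that share. Cytochrome P450 genes showed 11 in KO only, among them Cyp17a1, Cyp1a1, Cyp2f2 and Cyp3a11, and 5 in WT only. Defensin genes of the Defb family showed 6 in KO only and 1 in WT only. The Serpina family showed 5 in WT only, among them Serpina3n and Serpina3m, and 1 in KO only, and the claudins likewise 5 and 1. Olfactory receptors showed 36 in KO only and 32 in WT only. Serpina3 and Cyp genes include near-identical copies, so single members are uncertain. Xist of the X chromosome and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were in all 3 complete lists.

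The tests that follow were chosen after the results were seen, except the comparison of non-coding genes inside and outside coding genes, which was set before its result but after the counts per gene class. The surplus of non-coding genes in the E13.5 KO list over the E13.5 WT list was not what a single depth difference gave in simulated lists. The settings of those lists were not fitted to the real ones. The log2 ratio of KO-only to WT-only genes was higher for non-coding than for coding genes by 0.57 ± 0.12 (jackknife SE over chromosomes), and by 0.49 ± 0.11 without processed pseudogenes, which argues against pseudogenes as the whole source. Non-coding genes inside a coding gene on its own strand were 2.33 times as often in KO only as in WT only. Those outside coding genes were 1.48 times as often, a log2 difference of 0.66 ± 0.19. More reads from introns in the KO list would give such a difference. Placement used whole gene spans and did not separate introns from exons, so introns are not singled out. Of the inside genes, TEC genes were 257 of the 492 in KO only and 81 of the 211 in WT only. Outside, they were 84 of the 1181 and 66 of the 798. TEC genes thus carry part of the difference. Its size without TEC genes alone, with a spread, was not computed. At E13.5 the difference was 1.32 ± 0.23 in TEC genes (3.17 against 1.27 times) and 0.11 ± 0.27 without TEC, sense-intronic and processed pseudogene classes. It recurred for E15.5 KO against the same WT list (0.60 ± 0.20, with 0.53 ± 0.31 in those remaining classes, within 2 SE of 0 but close to the whole) and was -0.02 ± 0.19 between the KO lists, but the E13.5 WT library alone may differ: the stretch of the other WT list has 1 annotated non-coding gene, so genotype and library cannot be told apart.

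The 1390 genes that both E13.5 lists held and the E15.5 KO list lacked stood beside 1167 that both KO lists held and the E13.5 WT list lacked. The E13.5 WT and E15.5 KO lists are about equally long in total, at 25463 and 25474 genes. List length with 1 factor per list would make these numbers about equal, and their log2 ratio was 0.25 ± 0.069. By class the numbers went opposite ways, with 554 against 229 protein-coding and 832 against 933 non-coding genes. The 2 lists are also less equal by class, with 17108 and 16717 protein-coding and 8319 and 8717 non-coding genes. Among protein-coding genes the first group was 1.55 ± 0.083 times its expected number, so non-coding genes alone do not account for it. A shallower E15.5 KO library stays open, since neither check on it could decide. Its list had fewer protein-coding genes of its own than the E13.5 WT list (510 against 901, log2 ratio -0.82 ± 0.093). The 901 include the 554 genes to be explained, so that count is not independent of the pattern. Of genes in 1 complete list only, 347 were protein-coding in E13.5 WT and 281 in E15.5 KO. Simulated lists with E15.5 KO alone at a relative depth of 0.5 gave 1.18 ± 0.037 over all genes, against 1.35 ± 0.038 observed. That depth was not matched to the real lists, where E15.5 KO is about as long as E13.5 WT. Over the stretch of the E15.5 WT list, 5 genes of both E13.5 lists were missing from both E15.5 lists, 1 from E15.5 KO alone and 4 from E15.5 WT alone, which goes against a fault of the E15.5 KO library alone for those 5 but is too few for the whole group, so age, depth and library cannot be told apart.

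The markers of other cell types missing from the E15.5 KO list could reflect a shallower library. Against the E13.5 KO list its non-coding genes were fewer too (1644 against 2072, log2 ratio -0.33 ± 0.043), while against the E13.5 WT list they were more (2096 against 1698, 0.30 ± 0.031), and that WT list was itself short of non-coding genes, so depth is not excluded. Fewer cells of other types after sorting at E15.5 would also remove such markers, and 9 of 93 members were listed at E13.5 only, more than in 95.8% of random protein-coding lists (mean 4.69) but more than in only 35.3% of random lists of all genes, while counting both directions gave 83.0% and 2.42%. This one-way count replaced the count in both directions after both the members and that result were seen, no random list was matched on expression, and 0 of 14 immune and 0 of 8 mesothelium markers were lost. Sorting, depth and age cannot be told apart, since each age has 1 KO library.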
